A study of Mus musculus with 41 samples.

How the data were processed

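The analysis started from the deposited processed files of 1 mouse series: gene counts of 21 bulk RNA libraries, peak lists of 9 chromatin accessibility (ATAC) libraries, 2 merged and annotated peak tables, and 2 single-cell count matrices. No reads were aligned here. Per the labels, bulk RNA libraries were made by a modified Smart-seq2 protocol and read as paired ends of 150 bp, ATAC libraries with a TruePrep kit, and single-cell libraries with 10x 3' version 3 chemistry. The authors' processing notes name STAR, Bowtie2, HTSeq, MACS2, featureCounts, DESeq2 and HOMER with the mm10 genome. Which served which library, and their versions, is not given. Another 9 listed bulk RNA libraries of Lepr-positive stromal cells at 3 ages were not analysed.

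The values of the bulk RNA files are read counts per gene, whole numbers named as counts in the file names and by the authors. Their names read as duplicates removed, which no label states. Each file lists 53801 Ensembl gene ids, of which 53620 were given a symbol and 181 were not. The peak lists hold, per the file headers, the pileup (signal) at the summit, the fold enrichment over the local background (a ratio) and −log10 q. The file headers also record MACS 2.1.1.20160309 without a control library, no fragment model, a q threshold of 0.05 and at most 1 tag per position. The merged tables hold positions, the HOMER annotation and the distance in bp to the nearest transcription start site, and no signal of single samples. The single-cell matrices hold UMI counts from Cell Ranger 3.1.0, per the file headers.

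The labels give 3 libraries per bulk group. The series text calls them biological replicates, but nothing says that they came from separate animals or cultures, so every p-value here measures only the spread between these libraries. The labels conflict in 3 places: the source of the young primary stem cell libraries is written as stromal cells, the stem cell gate is written with CD48 positive, and the stromal sort is written without Tie2 in the protocol and without CD31 in the series text. The young primary stem cell libraries held Cxcl12 at 0.377, 1.99 and 0.334 CPM and Col1a1 at 3.39, 1.66 and 3.01 CPM, beside Kit at 149 CPM on average, and were used as stem cells.

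Stromal and stem cell libraries were fitted as separate datasets, all groups of a dataset together. Genes were kept with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at an adjusted p under 0.05. This left 14127 genes in stromal cells and 12741 in stem cells. The age by culture interaction is the age difference in 3D minus the age difference in primary cells on the log2 scale. A fold against a group with 0 counts is given as a floor, computed as if that group had held 3 counts. Where a group held 1 to 3 counts the CPM of both groups are given without a fold. Gene positions are of GRCm38.p6 (mm10).

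Gene lists were fixed before the data were examined, 27 for stromal cells and 27 for stem cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison. For each list the members past the threshold were counted after adjustment over all tested genes. Where adjustment over the list alone gave another count, that count is printed too. The stromal data also had hematopoietic, endothelial, pericyte, Schwann and erythroid lists as markers of other cells, and the stem cell data a stromal carry-over list.

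Named genes follow a rule fixed with the lists. Per comparison they come from the 6 called genes with the largest rise and the 6 with the largest fall among genes with at least 20 CPM in the higher group and groups that did not overlap, without unnamed models, pseudogenes, and histone, hemoglobin, immunoglobulin, ribosomal and mitochondrial genes. Up to 4 members of each described list with the smallest adjusted p were added, any member called against the majority of its list, and a fixed set of anchor genes. The text names part of these genes, chosen for length after the values were seen, and the tables hold all.

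Whether libraries with the same number were paired was checked by the correlation of residuals after the group means were removed. 2D and 3D stromal libraries of the same number resembled each other most (r = 0.144, 0.11 and 0.14, each closest to its own number in 6 of 6 comparisons). Young and old 3D stem cell libraries were also closest to their own number in 6 of 6, at r = 0.076, 0.044 and 0.012. The labels state no pairing, so the fit holds none, and a fit with the replicate number as a block was run beside it.

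Alternatives run for every bulk comparison were DESeq2 1.42.0 in place of edgeR, RLE and upper-quartile scaling, no filter, a filter at 5 CPM in 3 libraries, the replicate block, a test against a 2-fold change, only the 2 groups compared (not for the interaction), each library left out in turn, all libraries thinned to the smallest total, the markers of other cells left out, and for stromal cells only replicates 2 and 3. Lists were also tested with an estimated inter-gene correlation, with fry, with the replicate block, and with both an estimated correlation and the block. Upper-quartile scaling moved the median log2 fold change from −0.12 to −0.29 in 2D against primary stromal cells, from −0.02 to −0.12 in 3D against primary, and from 0.00 to −0.11 in the interaction. No other scaling moved it by more than 0.1.

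ATAC peaks were compared with bedtools 2.31.1. A region counted as shared with an overlap of 1 bp. The design planned a differential test per region, which was not made: the merged tables hold no signal, and the peak lists give it only where a peak was called. Regions of the merged tables were instead called present in a group when all 3 libraries had a peak and absent when 0 had. Peak numbers were compared by exact permutation of library labels, and the direction of RNA at genes nearest to regions by the two-sided Fisher exact test, with 0.5 added to each count of the odds ratio where a count was 0. The gene names of the annotation matched the RNA files for 31706 of 31812 entries (99.7%).

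Single cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were predicted with Scrublet in scanpy 1.11.5 (expected rate 0.1) and removed. Cells were grouped with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1. A cluster took the name of the class with the highest mean marker fold when at least 3 markers of it were raised 2-fold and seen in at least 10% of the cells, at least 1 was among the top 10 genes of the cluster, and no more than 1 marker of another class was. This naming rule was chosen after the clusters were seen, from marker sets fixed earlier. Gene lists were placed among 10000 random lists matched on expression, over genes with at least 5 CPM. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.

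The procedures were run on simulated counts with known changes. For 2D against primary stromal cells 7 of 98 genes changed 2-fold (7.1%) and 62 of 92 changed 4-fold (67.4%) were called, with 5 false among 74 calls. With 3D set to the midpoint, 0 of 98 genes changed 1.41-fold and 0 of 92 changed 2-fold were called in 3D against primary (0 calls) and in 3D against 2D (3 calls, all false). For old against young primary stem cells the recovery was 35 of 97 (36.1%) and 86 of 100, with 7 false among 128 calls, and for old against young 3D stem cells 30 of 97 (30.9%) and 86 of 100, with 5 false among 121. Of 51 lists the raised one was called and 0 unchanged ones were. Genes were drawn independently of each other, so this run cannot show how the list tests behave where genes vary together. The position measure gave 0.499 for a true 0.5, the correlation of age effects 0.901 for shared and −0.008 for unrelated effects. All 4 peak quantities were recovered on 2000 regions, and 96 of 100 random lists in the single-cell procedure fell inside the central 95%.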

Results

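The files hold expression and chromatin measurements of mouse bone marrow stromal cells and hematopoietic stem cells, taken freshly sorted or after culture. Stromal cells, sorted at 8 to 12 weeks with reporters of Kitl and Cxcl12, were measured fresh (primary), after culture on a flat surface (2D) and after culture in a soft GelMA gel (3D), with n = 3 RNA and n = 3 ATAC libraries per group. Stem cells were measured at a young age (8 to 12 weeks) and an old age (12 to 13 months), fresh and after 3D co-culture with stromal cells, with n = 3 RNA libraries in each of the 4 groups. Lineage-negative cells after 3D co-culture were also profiled as single cells, with 1 library from mice of 8 weeks and 1 from mice of 12 months. RNA libraries of primary, 2D and 3D stromal cells held 2.67 to 3.24, 8.35 to 14.7 and 6.98 to 23.3 M counts (M for 1e6). Stem cell libraries held 2.86 to 2.97 (primary young), 4.44 to 4.76 (primary old), 3.86 to 5.05 (3D young) and 5.00 to 6.07 M (3D old). Values below are CPM as mean ± SD (n = 3). Adjusted p are from the edgeR quasi-likelihood test (genes) or camera (lists), both Benjamini-Hochberg.

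Comparing 2D with primary stromal cells addresses what flat culture, with its medium, changes. Cxcl12, Kitl and Lepr fell by more than an order of magnitude. Cxcl12 (ENSMUSG00000061353.11, chromosome 6, 117168535 to 117181368), a chemokine that keeps stem cells in the marrow, fell 36.2-fold from 11640 ± 572 to 321 ± 69.3 CPM (adjusted p = 1.84e-07). Kitl (ENSMUSG00000019966.18, chromosome 10, 100015615 to 100100416), the ligand of the stem cell receptor Kit, fell 92.2-fold from 708 ± 98 to 7.71 ± 1.05 CPM (adjusted p = 3.32e-08). Reporters of Cxcl12 and Kitl were used to sort the primary cells. Lepr (ENSMUSG00000057722.17, chromosome 4, 101717137 to 101815352), the leptin receptor that marks this stromal population, fell 175-fold from 952 ± 148 to 5.47 ± 1.07 CPM (adjusted p = 3.27e-06). Acta2 (ENSMUSG00000035783.8, chromosome 19, 34240336 to 34255585), the smooth muscle actin of contractile fibroblasts, rose 45.9-fold from 121 ± 53.8 to 5551 ± 1010 CPM (adjusted p = 9.43e-07).

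Of 19 niche factors 14 fell, 1 rose and 4 were not past the threshold (list adjusted p = 0.000149). The macrophage cytokine Il34 fell 49.6-fold, the bone morphogenetic protein Bmp6 went from 152 ± 41.1 to 0.0717 ± 0.0684 CPM, and the macrophage growth factor Csf1 rose 2.57-fold. Of 25 Lepr-positive stromal identity genes 24 fell (list adjusted p = 9.78e-11): the complement inhibitor Serping1 402-fold, the BMP antagonist Chrdl1 643-fold and the transcription factor Ebf3 146-fold. Pdgfra, a receptor of mesenchymal progenitors, fell 28.3-fold. Contractile genes moved the other way, with 15 of 19 higher and 1 lower (list adjusted p = 0.000149, adjusted p = 0.313 with an estimated correlation). The actin-binding Tagln rose 49-fold, Tpm2 14.8-fold and Tagln2 4.98-fold, while the integrin linker Tln1 fell 1.41-fold (adjusted p = 0.12 and 0.0657 without 2D replicates 1 and 2). The YAP/TAZ targets were not called (11 of 22 higher, 4 lower, adjusted p = 0.0925). Among them the matricellular genes Ccn1 and Ccn2 rose 4.59-fold and 2.66-fold and the receptor kinase Axl 16-fold, while the growth factor carrier Igfbp3 fell 308-fold.

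In 2D 23 of 24 S phase genes (list adjusted p = 7.29e-07, adjusted p = 0.402 with an estimated correlation) and 23 of 24 G2/M genes rose (8.65e-07, adjusted p = 0.468 with an estimated correlation). The ribonucleotide reductase subunits Rrm1 and Rrm2 rose 9.19-fold and 20-fold, the spindle checkpoint kinases Bub1b and Bub1 43.6-fold and 27.2-fold, and the mitotic kinase Cdk1 15.5-fold. The largest rises were in Serinc2, S100a7a and Apol9a, which had 0 counts in primary cells (at least 167-fold, 138-fold and 72.6-fold). Next were the abscission gene Cep55 (0.0896 to 24.6 ± 2.81 CPM) and Krt7 (0.282 to 61.1 ± 3.86).

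Glycolysis had 14 of 17 members higher and 1 lower, 15 and 1 adjusted over the list alone (list adjusted p = 6.87e-06). The kinases Pgk1 and Pkm, which make ATP in its last steps, rose 19.1-fold and 24.1-fold, while the neuronal enolase Eno2 fell 25.8-fold (log2 −4.69, −4.07 without 2D replicate 3). Oxidative phosphorylation (23 of 24 higher, list adjusted p = 4.08e-08) and cholesterol synthesis (19 of 20 higher, 6.87e-06) rose too (adjusted p = 0.256 each with an estimated correlation). Cytochrome c (Cycs) rose 9.95-fold and the early sterol enzymes Fdps and Fdft1 13.6-fold and 15.8-fold (Fdft1 log2 3.98, 4.63 without primary replicate 2). Higher by their tests were also the unfolded protein response (12 of 18 higher, 2 lower, 0.0021), p53 targets (12 of 18 and 1, 12 and 2 adjusted over the list alone, 0.0314) and oxidative stress genes (10 of 19 and 3, 0.0357), with adjusted p = 0.402, 0.621 and 0.437 with an estimated correlation. The chaperone Hspa5 rose 2.51-fold and the amino acid enzyme Asns 12.2-fold. The death effector Bax rose 4.92-fold and the death receptor Fas fell 2.36-fold. Heme oxygenase Hmox1 rose 8.44-fold.

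Interferon response genes fell in 20 of 21 cases (list adjusted p = 2.28e-06, adjusted p = 0.402 with an estimated correlation). The signal transducer Stat2 fell 61.8-fold, the regulator Irf7 61.4-fold and the GTPase Iigp1 724-fold (log2 −9.50, −10.27 without 2D replicate 3). Adipogenic (2 of 17 higher, 9 lower, adjusted p = 0.117) and osteogenic genes (2 of 18 and 8, 0.346) were not called. The fat hormone Adipoq fell 440-fold, from 2053 ± 580 to 4.75 ± 1.71 CPM, the lipase Lpl 56.9-fold and the bone sialoprotein Ibsp 108-fold, while Col1a1, the main bone collagen, rose 6.3-fold. Senescence and secretory genes had 12 of 22 higher and 6 lower (adjusted p = 0.103, called with the replicate block), with the prostaglandin enzyme Ptgs2 187-fold higher. Collagens and glycoproteins had 6 of 25 higher and 13 lower, 7 and 13 adjusted over the list alone (adjusted p = 0.103). Fibronectin Fn1 rose 9.01-fold and the collagen VI chain Col6a1 fell 38.5-fold. Chondrogenic, matrix remodelling, integrin, immediate early, hypoxia and Schwann genes were not called either (adjusted p 0.221 to 0.863).

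In primary libraries hemoglobin made up 8.38 ± 0.631% of counts, against 0.00741% in 2D and 0.0203% in 3D, and the platelet factor Pf4 stood at 127, 381 and 1180 CPM in the 3 primary libraries. The erythroid list had 14 of 15 lower and 1 higher (list adjusted p = 1.44e-06, adjusted p = 0.346 with an estimated correlation), with carbonic anhydrase Car2 554-fold lower. All 14 endothelial genes fell (list adjusted p = 2.83e-06), such as the junction gene Pecam1 108-fold. The pericyte list had 8 of 12 lower and 2 higher (0.0433, adjusted p = 0.543 with an estimated correlation), with Notch3 248-fold lower and Cspg4 3.91-fold higher (log2 1.97, 2.67 without primary replicate 1). The platelet genes Gp9 and Clec1b had 0 counts in 2D and fell at least 562-fold and 548-fold. So did the adhesion gene Negr1 (at least 469-fold). The hematopoietic list was not called (adjusted p = 0.085, called with the replicate block), with 6 of 18 members lower, the neutrophil gene S100a8 212-fold.

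In the edgeR test 9788 of 14127 genes were past the threshold (4605 higher, 5183 lower). Of the called lists, niche factors, Lepr-positive identity, glycolysis and endothelial genes hold with an estimated correlation and the other 11 do not, and with the replicate block as well only Lepr-positive identity does. Replicate 1 of each stromal group had more Xist than the others.

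**Figure D1:**
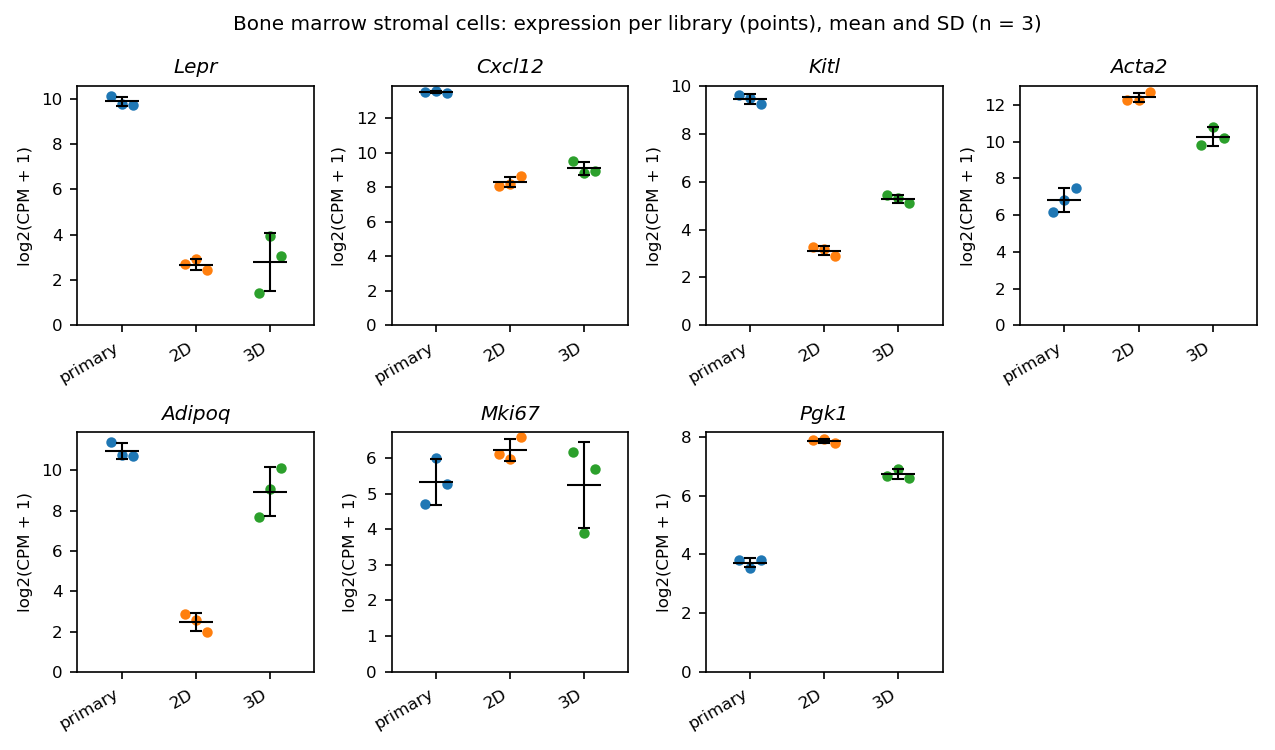
Expression of 7 genes in single stromal libraries as log2(CPM + 1) for primary, 2D and 3D cells. Points are libraries and bars mean ± SD (n = 3).

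Comparing 3D with primary stromal cells asks what differs after gel culture. Lepr stood at 7.82 ± 6.45 CPM, 129-fold lower than in primary cells (adjusted p = 8.41e-06), Cxcl12 at 560 ± 159 CPM, 20.8-fold lower (7.43e-07), and Kitl at 38.2 ± 4.8 CPM, 18.5-fold lower (2.34e-07). Acta2 was 10.7-fold higher at 1298 ± 470 CPM (adjusted p = 1.99e-05), and Ccn2, a matricellular gene induced by tension, was 3.27-fold lower. The fibronectin gene Fn1 rose 26.3-fold, Col1a1 21.4-fold, the periosteal protein Postn 12.2-fold, the gelatinase Mmp2 17.9-fold and its inhibitor Timp1 17.2-fold, and the matrix remodelling list was not called.

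Of the niche factors 13 of 19 fell and 3 rose (list adjusted p = 0.000526). Bmp6 fell 607-fold and Il34 32.6-fold, while the matrix cytokine Spp1 rose 18.4-fold and the Notch-like ligand Dlk1 went from 0.282 to 79.3 ± 98.3 CPM. Identity genes fell in 21 of 25 cases and rose in 2 (list adjusted p = 2.12e-08): Serping1 fell 40.3-fold, Ebf3 78.1-fold and Pdgfra 4.49-fold (log2 −2.17, −2.76 without 3D replicate 1), and the imprinted RNA H19 rose 14.7-fold (3.88, 9.98 without primary replicate 3). Adipogenic genes were not called as a list (12 of 17 higher, 4 lower, adjusted p = 0.163, called with the replicate block). The fatty acid carrier Fabp4 rose 6.2-fold and the adipokine Retn 143-fold (log2 7.16, 6.55 without 3D replicate 3), while Lpl fell 2.68-fold, the adipocyte factor Cebpa 2.87-fold and Adipoq 3.34-fold to 616 ± 458 CPM (log2 −1.74, −2.43 without 3D replicate 3; adjusted p = 0.059 without 3D replicate 2). The lipid droplet gene Plin4 had 0 counts in primary cells and rose at least 97.4-fold.

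Senescence and secretory genes were higher in 15 of 22 cases and lower in 3 (list adjusted p = 0.0291, adjusted p = 0.344 with an estimated correlation). The cell cycle inhibitor Cdkn2b rose 178-fold, its neighbour Cdkn2a at least 90-fold and the attractant Ccl7 13.4-fold (log2 3.75, 3.12 and 4.35 without 3D replicates 1 and 2), while the interleukin Il6 fell 5.28-fold. S phase rose in 16 of 24 members, 17 adjusted over the list alone (list adjusted p = 0.00203, adjusted p = 0.595 with an estimated correlation), and G2/M in 21 of 24 (0.000337, adjusted p = 0.595 with an estimated correlation), with Rrm2 4.4-fold and Cdk1 5.5-fold higher. Interferon genes fell in 16 of 21 cases, 17 adjusted over the list alone (3.5e-06, adjusted p = 0.451 with an estimated correlation), Irf7 12.7-fold (log2 −3.67, −4.28 without 3D replicate 3).

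Glycolysis had 13 of 17 higher in 3D and 1 lower, 15 and 1 adjusted over the list alone (list adjusted p = 9.02e-06), with Pgk1 8.68-fold and Pkm 19.7-fold higher. All 24 oxidative phosphorylation genes (2.61e-09) and 18 of 20 cholesterol genes rose, 19 adjusted over the list alone (9.04e-07), with adjusted p = 0.193 and 0.178 with an estimated correlation. Cox4i1 rose 3.27-fold and Fdft1 and Sqle, of sterol synthesis, 25.4-fold and 13.4-fold (Fdft1 log2 4.66, 5.31 without primary replicate 2). The unfolded protein response (11 of 18 higher, 2 lower, 0.0155), p53 targets (14 of 18 higher, 0.00196) and oxidative stress genes (13 of 19 and 2, 0.00339) rose by their tests, with adjusted p = 0.505, 0.592 and 0.344 with an estimated correlation. The kinase homologue Trib3 rose 60-fold (log2 5.91, 6.82 without primary replicate 3 and 5.11 without 3D replicate 3), the p53 target Phlda3 6.74-fold and the quinone reductase Nqo1 21.5-fold.

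Erythroid genes fell in 14 of 15 cases (4.8e-08, adjusted p = 0.28 with an estimated correlation), with the heme enzyme Alas2 757-fold lower (log2 −9.56, −8.96 without 3D replicate 3). The ammonium transporter Rhag fell at least 470-fold, Gp9 at least 869-fold and the granule gene Ngp went from 53.4 to 0.0237 CPM. Endothelial genes fell in 13 of 14 (1.53e-06), Pecam1 154-fold and the VEGF receptor Flt1 153-fold, and pericyte genes in 7 of 12 with 2 higher (0.0131, adjusted p = 0.505 with an estimated correlation), Rgs5 63.6-fold lower. Several genes with the largest rise are made by macrophages: the cytokine Tnf (at least 187-fold, 51.9 ± 78.3 CPM), the receptor Csf1r (at least 119-fold, 33.1 ± 49.2 CPM) and Tnfsf9 (at least 96.7-fold). In these genes the SD is above the mean (log2 11.87, 11.23 and 10.93, and 8.80, 8.32 and 8.24 without 3D replicate 3), and the macrophage lysozyme Lyz2 stood at 171, 659 and 7250 CPM in 3D replicates 1, 2 and 3. The prolactin-like Prl2c2 went from 0.0896 to 200 CPM. Hematopoietic genes were not called (5 of 18 higher, 6 lower, adjusted p = 0.211; the median log2 is 0.33, the mean −0.89 and the test points down).

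Contractile genes were not called (10 of 19 higher, 2 lower, adjusted p = 0.122), nor were YAP/TAZ targets (9 of 22 and 6, 0.792). Matrix remodelling genes were not called (7 of 18 and 7, 0.787), where the median log2 is −0.15, the mean 0.61 and the test points down. In all 8800 of 14127 genes passed in edgeR (4367 higher, 4433 lower). Niche factors, Lepr-positive identity, glycolysis and endothelial genes hold with an estimated correlation and the other 11 called lists do not, and 0 hold with the replicate block as well.

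Comparing 3D with 2D stromal cells addresses what the gel and UVA change. Lepr-positive identity genes were higher in the gel. Acta2 was 4.28-fold lower in 3D (1298 ± 470 against 5551 ± 1010 CPM, adjusted p = 0.00164), and the muscle ankyrin repeat gene Ankrd1 (ENSMUSG00000024803.8, chromosome 19, 36111965 to 36119844), a target of YAP/TAZ, was 84.3-fold lower (13.3 ± 11.7 against 1075 ± 97.7 CPM; log2 −6.40, −7.27 without 3D replicate 2). Fabp4 was 25.6-fold higher (2554 ± 921 against 99.9 ± 11.2 CPM, adjusted p = 9.74e-06). Kitl was 4.98-fold higher (adjusted p = 3.79e-05) and Cxcl12 1.74-fold higher (adjusted p = 0.0207), and Lepr was not past the threshold (1.35-fold, adjusted p = 0.591). Without 3D replicate 1 the adjusted p of Lepr was 0.0334, without 3D replicate 2 its log2 change was −0.24, and without 2D replicates 1 and 2 that of Cxcl12 was 0.108 and 0.0937.

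The contractile list had 15 of 19 members lower, 16 adjusted over the list alone (list adjusted p = 1.41e-08, adjusted p = 0.147 with an estimated correlation). Tagln fell 7-fold, Tagln2 3.7-fold and the focal adhesion gene Zyx 2.79-fold. The YAP/TAZ list was lower by its test (0.0392, adjusted p = 0.496 with an estimated correlation), with 9 of 22 members lower and 4 higher: Ccn2 fell 8.68-fold and Crim1 3.68-fold, and Igfbp3 and tissue factor F3 rose 3.85-fold and 3.15-fold. The cardiac troponin Tnnt2 was 52.5-fold lower (log2 −5.71, −5.07 and −7.74 without 3D replicates 1 and 2), the vessel-constricting peptide gene Edn1 113-fold (−6.82, −7.97 without 3D replicate 2) and Krt7 38.2-fold. Integrins were not called as a list (3 of 23 higher, 7 lower, adjusted p = 0.0716), although the fibronectin receptor subunits Itga5 and Itgb1 fell 3.53-fold and 2.51-fold. Cell cycle genes fell: 20 of 24 S phase genes fell, 22 adjusted over the list alone (8.75e-11, adjusted p = 0.33 with an estimated correlation), and 17 of 24 G2/M genes (6.04e-09, adjusted p = 0.496 with an estimated correlation), with Rrm2 4.56-fold, Rrm1 3.68-fold, Aurka 4.96-fold and Ccnb1 3.2-fold lower.

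Identity genes rose in 20 of 25 cases, 22 adjusted over the list alone (list adjusted p = 1.05e-09), with Serping1 9.99-fold, Chrdl1 30.3-fold, Il1rn 45.6-fold and Lpl 21.2-fold higher. Niche factors rose in 11 of 19 and fell in 1, 13 and 1 adjusted over the list alone (0.00114, adjusted p = 0.108 with an estimated correlation): the vessel-stabilising ligand Angpt1 14.2-fold, the growth factor Gas6 3.97-fold and Spp1 8.54-fold higher (Spp1 log2 3.09, 2.47 without 3D replicate 2), Csf1 1.9-fold lower. All 17 adipogenic genes rose (5.75e-09, adjusted p = 0.33 with an estimated correlation), Adipoq 132-fold (adjusted p = 6.54e-05), Adig 334-fold and Cfd 328-fold (551 ± 724 CPM). Without 3D replicate 3 their log2 changes were 6.30, 7.40 and 6.32 in place of 7.04, 8.38 and 8.36. Osteogenic genes rose in 14 of 18 cases (0.00153, adjusted p = 0.582 with an estimated correlation), with Ibsp 110-fold (11870 ± 14500 against 108 CPM) and osteocalcin Bglap 184-fold higher (524 ± 636 CPM). Without 3D replicate 3 their log2 changes were 5.09 and 5.84 in place of 6.79 and 7.52. The chondrogenic list was not called (5 of 10 higher, 1 lower, adjusted p = 0.0593, called with the replicate block), with the cartilage factor Sox9 5.01-fold higher (log2 2.32, 1.71 without 3D replicate 1). Collagens and glycoproteins rose in 14 of 25 and fell in 2, 15 and 2 adjusted over the list alone (0.000971, adjusted p = 0.342 with an estimated correlation). The collagen VI chains Col6a1 and Col6a2 rose 23-fold and 32.1-fold and Col3a1 5.51-fold, while the crosslinking enzyme Loxl2 fell 6.11-fold.

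Interferon genes rose in 14 of 21 cases, 15 adjusted over the list alone (0.000444, adjusted p = 0.496 with an estimated correlation), Iigp1 23.4-fold (log2 4.55, 5.36 without 2D replicate 3 and 3.86 without 3D replicate 3). Glycolysis fell in 9 of 17 and rose in 2, 11 and 2 adjusted over the list alone (0.00218, adjusted p = 0.147 with an estimated correlation), Pgk1 2.2-fold and Eno1 2.62-fold lower, Eno2 9.21-fold higher. Macrophage genes were among the largest rises, the scavenger receptor Marco 331-fold (102 ± 157 CPM; log2 8.37, and 5.13 without 3D replicate 3) and the integrin Itgad from 0.0909 to 21.6 CPM. They were highest in 3D replicate 3, where Csf1r stood at 90 CPM against 4.63 and 4.84 and complement C1qb at 348 CPM against 6.81 and 23.8. Hematopoietic markers as a list were not called (5 of 18 higher, adjusted p = 0.221, called with the replicate block), with Lyz2 13.1-fold higher (log2 3.71, and 1.00 with adjusted p = 0.12 without 3D replicate 3; adjusted p = 0.0842, 0.0638 and 0.075 without 2D replicates 1, 2 and 3). Nor was the unfolded protein response (3 of 18 higher, 8 lower, adjusted p = 0.0716), with the chaperone Manf 2.41-fold lower.

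In edgeR 3961 of 14127 genes passed (2174 higher, 1787 lower). Leaving out 1 library lowered this count to 2168, 2349 and 2229 without 2D replicates 1, 2 and 3. Of the 11 called lists only Lepr-positive identity holds with an estimated correlation, with the replicate block as well.

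A position measure places 3D between the other groups, with 0 for primary and 1 for 2D. Over the 9788 genes that differed between 2D and primary cells the median position of 3D was 0.758 (interquartile range 0.525 to 0.982). Genes lower in 2D, such as Kitl and Adipoq, had a median of 0.778 and genes higher in 2D, such as Acta2 and Cdk1, a median of 0.741. Of all 9788 genes 23.1% lay nearer to primary (under 0.5), 4.85% under 0 and 23% over 1. The 3 libraries of 3D gave 0.797, 0.75 and 0.745 (SD 0.029).

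**Figure D2:**
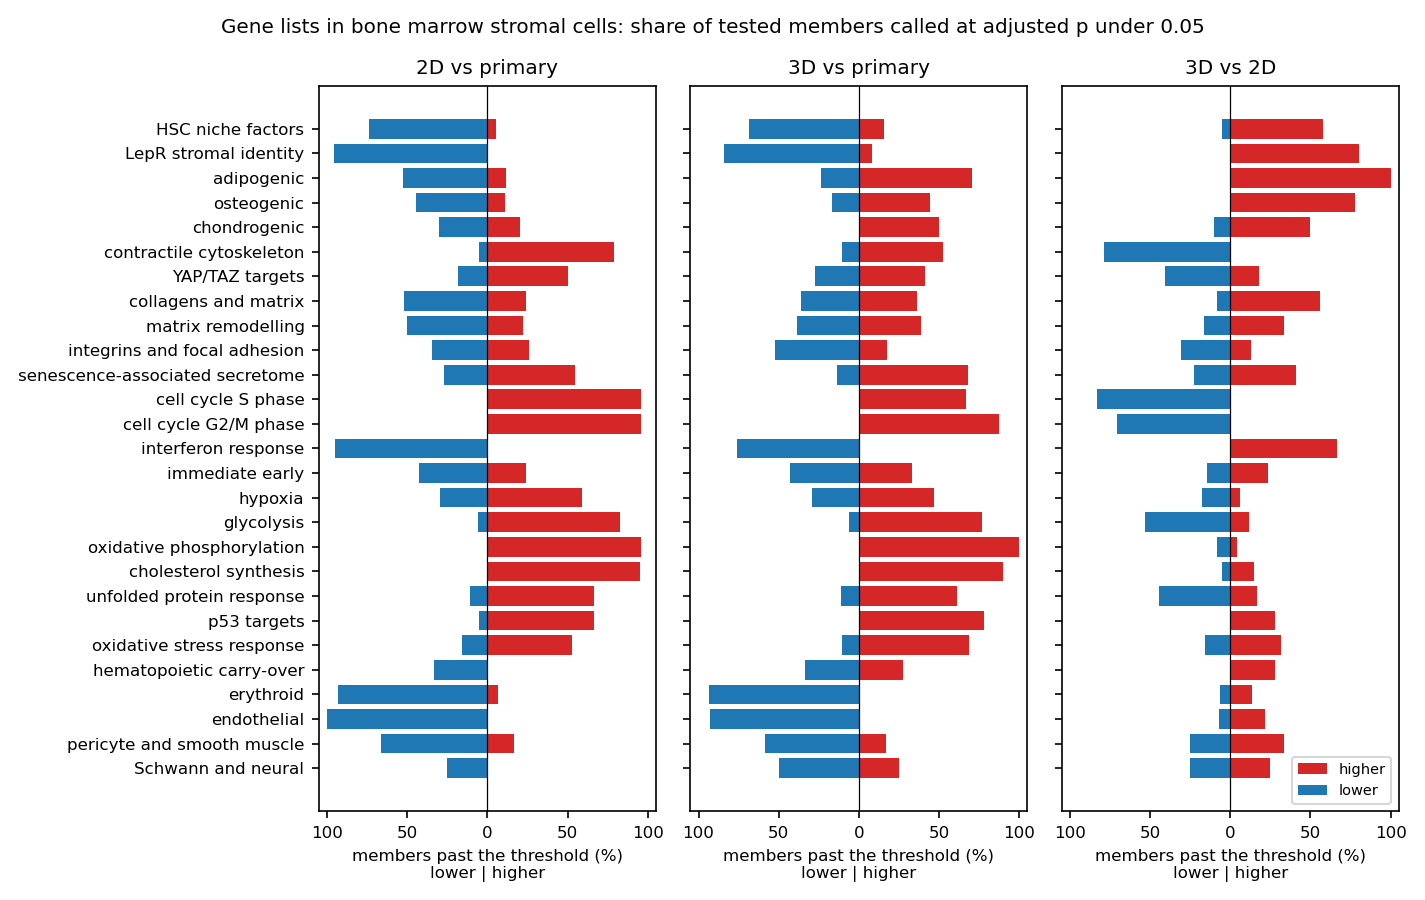
Share of tested members of each of 27 gene lists called higher (right) or lower (left), in percent, for 2D against primary, 3D against primary and 3D against 2D.

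The comparison of old with young primary stem cells addresses what age changes before any culture. Socs3, a brake on cytokine signalling, rose 5.93-fold from 2.94 ± 1.59 to 17.8 ± 4.81 CPM, the transcription factor Fos 3.18-fold from 54.4 ± 15.8 to 173 ± 7.95 CPM and Junb 2.37-fold from 56.6 ± 10.2 to 134 ± 13.3 CPM. Selp (ENSMUSG00000026580.16, chromosome 1, 164115264 to 164150026), P-selectin, a known marker of aged stem cells, rose 4.99-fold from 7.35 ± 8.7 to 37.2 ± 13.5 CPM (adjusted p = 0.006; log2 2.32, 4 without young replicate 3). Hlf (ENSMUSG00000003949.16, chromosome 11, 90336535 to 90390917), a transcription factor of long-term stem cells, fell 2.1-fold from 318 ± 49.9 to 151 ± 12.2 CPM (adjusted p = 0.00493). The Notch target Hes1 fell 11.5-fold from 73.4 ± 36.3 to 6.36 ± 1.43 CPM.

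The immediate early list had 9 of 16 members higher and 0 lower, 10 adjusted over the list alone (list adjusted p = 0.000182, adjusted p = 0.709 with an estimated correlation), among them Egr1, 2.32-fold higher. Genes of stem cell ageing rose in 13 of 30 cases and fell in 2, 15 and 3 adjusted over the list alone (0.00065, adjusted p = 0.709 with an estimated correlation). The scramblase Plscr2 rose 4.02-fold, the growth hormone receptor Ghr 5.87-fold and the metal binder Mt1 2.9-fold, while the prostaglandin receptor Ptger4 fell 4.74-fold. Of the anchors, Kit fell 1.37-fold from 149 ± 6.2 to 108 ± 2.61 CPM, the leukocyte phosphatase Ptprc fell 1.7-fold and the proliferation marker Mki67 rose 1.77-fold (adjusted p = 0.0397). Not past the threshold were Vwf (11.8 and 22.4 CPM, adjusted p = 0.0512), Slamf1 (0.178), Cd48 (0.11), Cdkn1c (0.0605), Procr (0.731) and Ly6a (0.236). Without 1 library Vwf (0.0322, young replicate 3), Cdkn1c (0.0333, old replicate 3) and Ly6a (0.0311, young replicate 1) passed. Mki67 did not pass without young replicates 1 and 3 (0.0786 and 0.104) or without old replicates 1, 2 and 3 (0.0948, 0.0865 and 0.0553).

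The largest rise was in Wfdc17 (0 counts in young, at least 79.5-fold). Next were the oxysterol enzyme Cyp39a1 (0.223 to 30.7 ± 10.3 CPM), the RNA-binding Zcchc14 (67.2-fold, 32.9 ± 39 CPM), the RhoGAP Dlc1 (0.347 to 21.5 ± 24.7 CPM) and Ccnj (46.7-fold). The nicotinic receptor Chrnb4, the integrin ligand Npnt and Clec4a1 fell to 0 counts (at least 304-fold, 106-fold and 98.4-fold). Without young replicate 1 the log2 changes of Chrnb4 and Clec4a1 were −9.94 and −8.07 in place of −11.07 and −9.44. Next were Adamts14 (45.1 ± 54.6 to 0.0692 CPM), Ovgp1 (24.8 ± 9.02 to 0.0692 CPM) and Dennd2a (59.6-fold, 78.4 ± 124 CPM). In Zcchc14, Dlc1, Adamts14 and Dennd2a the SD is above the mean of the higher group. The log2 change of Zcchc14 was 4.43 in place of 6.07 without old replicate 3 and that of Dennd2a −2.42 in place of −5.90 without young replicate 2.

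Within lists that were not called, quiescence genes had 2 of 15 higher and 4 lower (adjusted p = 0.944), with the forkhead factors Foxo1 6.03-fold higher (log2 2.59, 3.82 without young replicate 2) and Foxo3 1.67-fold lower (adjusted p = 0.0557 without young replicate 1). Long-term stem cell genes had 1 of 24 higher and 3 lower (0.868), G2/M 7 of 24 higher (0.0572), with Bub1 6.1-fold higher, and S phase 5 of 24 and 2 (0.573), with Mcm3 1.72-fold higher and Mcm4 1.97-fold lower. Granulocyte-monocyte genes had 6 of 18 and 1 (0.191), with the progenitor gene Ms4a3 5.04-fold higher and the cytokine receptor Csf2rb 6.55-fold lower, and megakaryocyte genes 3 of 17 and 2 (0.868), with the integrin Itgb3 5.07-fold higher. The other lists were not called either (adjusted p 0.113 to 0.973). The median, mean and test differ in sign for interferon, glycolysis, unfolded protein, erythroid, megakaryocyte, homing, DNA repair, NF-kB, autophagy, MYC and stromal carry-over genes.

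In edgeR 3465 of 12741 genes passed (1692 higher, 1773 lower). Neither called list holds with an estimated correlation.

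Comparing 3D with primary stem cells addresses what gel co-culture changes at each age. Glycolysis and hypoxia genes rose at both. In young cells Pgk1 (ENSMUSG00000062070.12, chromosome X, 106187100 to 106203699), an enzyme of glycolysis, rose 9.03-fold from 43 ± 8.01 to 388 ± 19.9 CPM, and the hypoxia gene Bnip3, which guides removal of mitochondria, 20.8-fold from 7.95 ± 3.47 to 164 ± 9.95 CPM. Ly6a, the Sca-1 antigen used in the sort, rose 2.65-fold from 287 ± 35.5 to 762 ± 51.8 CPM (adjusted p = 7.28e-07), and Kit, also used in the sort, fell 2.66-fold to 56 ± 3.9 CPM (adjusted p = 1.77e-06).

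In young cells 16 of 17 glycolysis genes rose, with 1 lower adjusted over the list alone (list adjusted p = 3.27e-12), Aldoa 5.33-fold and Pkm 6.27-fold. Hypoxia genes rose in 11 of 18 and fell in 1 (3.46e-05), with the glucose transporter Slc2a1 3.89-fold and the oxygen sensor Egln3 66.3-fold higher (Egln3 log2 6.05, 7.5 and 5.46 without primary young replicates 2 and 3) and Ndrg1 4.83-fold lower (log2 −2.27, −1.57 without primary young replicate 3). Oxidative phosphorylation rose in 21 of 24, 22 adjusted over the list alone (4.29e-11), Uqcrq 2.56-fold. G2/M genes rose in 19 of 24, 20 adjusted over the list alone (2.4e-10), with Ccnb1 6.6-fold and the survivin gene Birc5 3.66-fold higher, and S phase genes in 13 of 24 with 1 lower (0.000585, adjusted p = 0.185 with an estimated correlation), Rrm2 3.93-fold higher. Senescence and secretory genes rose in 6 of 9 and fell in 1 (0.000683), with the cell cycle inhibitor Cdkn1a 14.2-fold higher.

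Long-term stem cell genes fell in 13 of 24 young cases and rose in 2 (0.000968), ageing genes fell in 17 of 30 and rose in 5, 18 and 6 adjusted over the list alone (0.0156), and megakaryocyte genes fell in 10 of 17 and rose in 1 (0.00342). With an estimated correlation these lists have adjusted p = 0.146, 0.282 and 0.185. The platelet matrix gene Mmrn1 fell 66-fold, the aldehyde enzyme Aldh1a1 48.4-fold and the platelet receptor gene Gp1bb at least 75.8-fold, while Selp rose 18.9-fold to 141 ± 10.9 CPM (log2 4.24, and 5.93 without primary young replicate 3). Interferon genes fell in 14 of 22, 15 adjusted over the list alone (6.36e-05), and erythroid genes in 7 of 10 with 1 higher (0.0171), each with adjusted p = 0.185 with an estimated correlation. The GTPase Gbp2 fell 4.48-fold. The erythroid factor Klf1 fell at least 46.1-fold, and the beta hemoglobin Hbb-bt rose 43-fold from 46.9 to 2019 CPM. Granulocyte-monocyte genes rose in 12 of 18 and fell in 3, 13 and 3 adjusted over the list alone (0.0171), the unfolded protein response rose in 7 of 18 with 1 lower (0.0316) and p53 targets in 6 of 17 with 1 lower (0.0316), each with adjusted p = 0.185 with an estimated correlation. The lysosomal Cd68 rose 6.63-fold, Ms4a3 4.52-fold, Asns 4.54-fold and Bax 2.88-fold, and the neutrophil gene S100a9 fell 10.3-fold.

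The largest rises in young cells were in Wfdc17 (0 counts in primary, at least 2050-fold, 709 ± 117 CPM), the differentiation inhibitor Id3 (at least 297-fold), the macrophage elastase Mmp12 (at least 127-fold) and the chemokine Ccl2 (at least 83-fold) (log2 of the last 2 10.57 and 9.96, 9.33 and 9.12 without 3D young replicate 3). Mmp12 and the macrophage gene Gpnmb were highest in 3D young replicate 3 (Mmp12 14.6, 22 and 95.1 CPM). The largest falls were in the caveola gene Cavin2 (at least 243-fold), Sorbs2 (at least 218-fold), Pla2g4c (at least 129-fold; log2 −10.01, −7.53 without primary young replicate 2) and carbonic anhydrase Car1 (at least 104-fold). Other anchors were Procr (1.77-fold lower), the inhibitor Cdkn1c (3.59-fold lower), Vwf (2.05-fold lower, adjusted p = 0.0238) and Cd48 (5.25-fold higher; log2 2.39, and 1.48 without 3D young replicate 1), with Slamf1 (0.557), Ptprc (1) and Mki67 (0.16) not past the threshold. The adjusted p of Mki67 was 0.00308 without primary young replicate 2. That of Vwf was 0.0568 and 0.104 without primary young replicates 2 and 3 and 0.0725 and 0.0951 without 3D young replicates 1 and 2. Quiescence genes were not called (3 of 15 higher, 7 lower, adjusted p = 0.402), nor were immediate early genes (7 of 16 and 2, 0.0583), although Socs3 rose 20-fold and Junb 4.71-fold. Median, mean and test differ in sign for quiescence, lymphoid and mast cell genes.

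In old cells 16 of 17 glycolysis genes rose (1.24e-14), Aldoa 5.5-fold and Pgk1 8.49-fold, and 12 of 18 hypoxia genes with 1 lower, 14 and 1 adjusted over the list alone (1.01e-06), Bnip3 16.8-fold and the oxidase Ero1l 14-fold. Oxidative phosphorylation rose in 21 of 24 (1.7e-10), Cox6c 2.02-fold. G2/M genes rose in 20 of 24, 21 adjusted over the list alone (1.2e-09), and ribosomal protein genes in 16 of 22, with 1 lower adjusted over the list alone (1.01e-06). With an estimated correlation they have adjusted p = 0.0661 and 0.144. Ccnb1 rose 4.65-fold and the small subunit genes Rps18 and Rps14 1.71-fold and 1.65-fold. The p53 targets rose in 7 of 17 with 1 lower, 8 and 1 adjusted over the list alone (0.00466), and the unfolded protein response in 7 of 18 (0.0186), with adjusted p = 0.116 and 0.12 with an estimated correlation. Phlda3 rose 32.9-fold (log2 5.04, 6.14 and 4.45 without primary old replicates 1 and 2) and Asns 4.14-fold.

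Long-term stem cell genes fell in 15 of 24 old cases and rose in 2 (3.2e-05), and ageing genes fell in 22 of 30 and rose in 4, 23 and 4 adjusted over the list alone (2.53e-06), with adjusted p = 0.0814 and 0.0909 with an estimated correlation. Gata2 fell 3.32-fold, Mmrn1 56.8-fold and Fhl1 34.1-fold, and the metal binder Mt2 rose 24.6-fold. Interferon genes fell in 16 of 22 (1.66e-07), megakaryocyte genes in 10 of 17 with 2 higher, 11 and 2 adjusted over the list alone (0.000702), and erythroid genes in 7 of 10 with 2 higher (0.036). With an estimated correlation they have adjusted p = 0.101, 0.144 and 0.219. The antiviral Ifit1 fell 18-fold, Usp18 9-fold and Hba-a1 122-fold (Hba-a1 log2 −6.93, −6.16 without primary old replicate 2), and Hbb-bt rose 23.8-fold.

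Vwf (ENSMUSG00000001930.17, chromosome 6, 125552948 to 125686679), the platelet adhesion gene of platelet-biased stem cells, fell 46.5-fold in old cells, from 22.4 ± 1.94 to 0.464 ± 0.178 CPM (adjusted p = 1.68e-06). Ly6a rose 2.77-fold and Selp 3.76-fold, Kit fell 2.08-fold, Procr 1.75-fold and Cdkn1c 3.68-fold, and Ptprc rose 1.64-fold, while Slamf1 (0.496), Cd48 (0.231) and Mki67 (0.865) were not past the threshold. The largest rises were in the mitochondrial Mgarp (at least 137-fold), Ppm1j (at least 120-fold), the lymphoid polymerase Dntt (0.0701 to 23.9 CPM), Egln3 (68.5-fold) and the nuclear receptor Nr6a1 (67.5-fold; log2 6.08, 5.46 without 3D old replicate 2). The largest falls were in the imprinted RNA Meg3 (at least 384-fold, 74.1 ± 71.7 CPM in primary; log2 −11.33, −10.14 without primary old replicate 3), the hormone receptor Lhcgr (at least 126-fold), the Wnt inhibitor Sfrp1 (46.3 to 0.132 CPM) and Sult1a1 (266-fold; log2 −8.05, −7.42 and −9.64 without 3D old replicates 1 and 2). Hes1 rose 34.4-fold and Csf2rb 16.7-fold, and the immediate early gene Fos fell 3.23-fold. Immediate early (4 of 16 higher, 7 lower, adjusted p = 0.746) and quiescence genes (4 of 15 and 5, 0.746) were not called. Median, mean and test differ in sign for the quiescence list.

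In edgeR 6100 of 12741 genes passed in young cells (2930 higher, 3170 lower) and 5112 in old cells (2556 higher, 2556 lower). The 2 comparisons share no library: 1509 genes such as Pgk1 and Bnip3 were higher in both (588 if calls were independent), 1359 such as Mmrn1 lower in both (636), and 305 moved in opposite directions (1224). Across genes the log2 fold changes had a Pearson correlation of 0.454. With an estimated correlation glycolysis, hypoxia and oxidative phosphorylation hold at both ages, G2/M and senescence and secretory genes in young cells, and none of the other called lists, and with the replicate block as well the first 3 and, in old cells, ageing genes do.

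**Figure D3:**
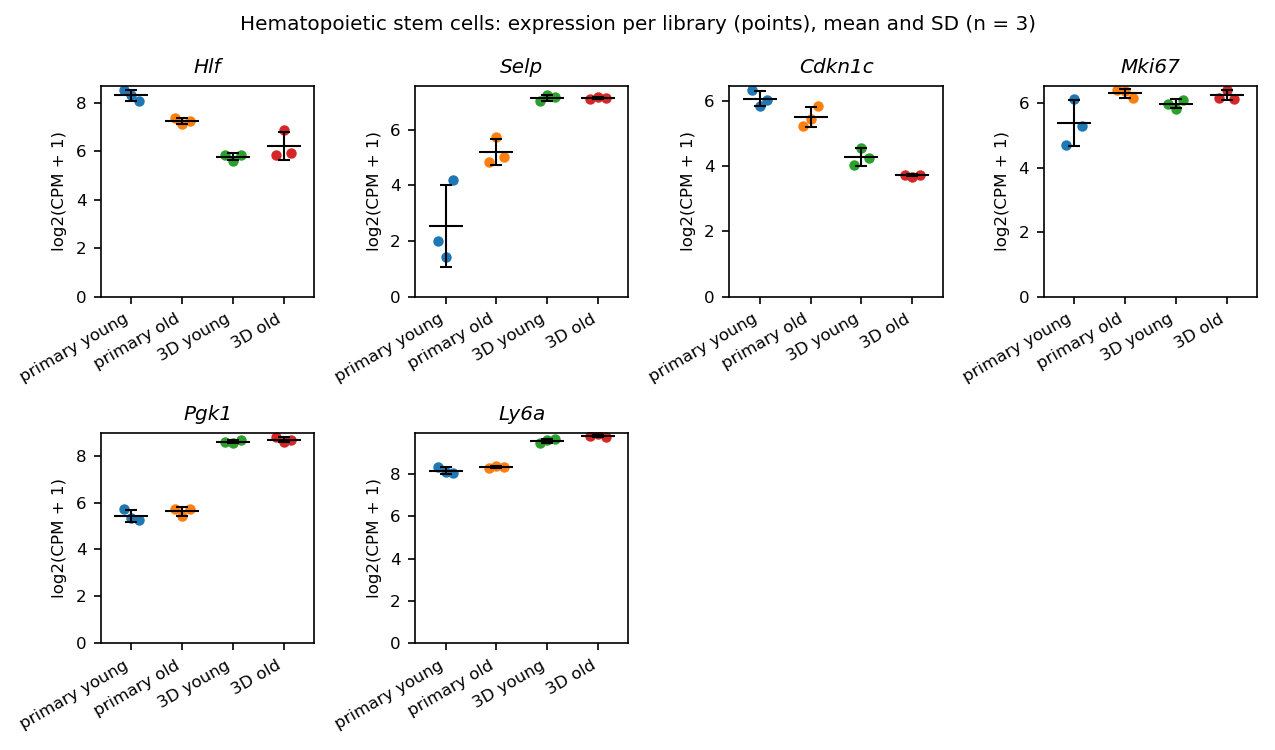
Expression of 6 genes in single stem cell libraries as log2(CPM + 1) for primary young, primary old, 3D young and 3D old cells, with mean ± SD (n = 3).

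Comparing old with young 3D stem cells addresses which age differences are seen in the gel. Fewer genes passed than in primary cells, and the marker Selp, different by age in primary cells, was level (140 and 141 CPM, adjusted p = 0.995). Vwf was 12-fold lower in old cells (0.464 ± 0.178 against 5.79 CPM, adjusted p = 0.00218), and the SLAM receptor gene Slamf1 2.07-fold higher (adjusted p = 0.0479). The ageing genes Plscr2 and Aldh1a1 were 8.5-fold and 8.46-fold higher in old cells and Ehd3 5.69-fold lower (log2 −2.51, −1.91 without young replicate 2). Kit, Cd48, Ptprc, Procr, Mki67, Cdkn1c (adjusted p = 0.122) and Ly6a (0.185) were not past the threshold, and Slamf1 was not without young replicates 1, 2 and 3 (0.146, 0.0876 and 0.101) or old replicates 2 and 3 (0.192 and 0.112).

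Ribosomal protein genes were higher in old cells in 6 of 22 cases, 10 adjusted over the list alone (list adjusted p = 1.69e-07), and p53 targets in 2 of 17, 5 adjusted over the list alone (0.000925). With an estimated correlation they have adjusted p = 0.204 and 0.201. Rpl11 rose 1.36-fold, Trp53inp1 12.3-fold and the death gene Pmaip1 19.9-fold (log2 4.31, 5.86 without young replicate 1). Hypoxia genes rose in 2 of 18, oxidative stress genes in 3 of 18 and quiescence genes in 3 of 15, 4 adjusted over the list alone (0.0313 each), with adjusted p = 0.201, 0.201 and 0.372 with an estimated correlation. The demethylase Kdm3a rose 1.79-fold, Mt1 2.58-fold, Mt2 18.4-fold (log2 4.20, 3.53 and 6.51 without young replicates 1 and 3) and Hes1 2.22-fold. Interferon genes fell in 6 of 22, 7 adjusted over the list alone, and S phase genes in 1 of 24, 2 adjusted over the list alone (0.0313 each), with adjusted p = 0.444 and 0.431 with an estimated correlation. Ifit1 fell 4.87-fold and the replication gene Rpa2 1.57-fold. Senescence and secretory genes fell in 3 of 9, 4 lower and 1 higher adjusted over the list alone (0.0375, adjusted p = 0.201 with an estimated correlation), with the chemokine Ccl2 15.7-fold lower (log2 −3.98, −3.10 without young replicate 3 and −4.81 without old replicate 2). The calls of some of these genes are lost with 1 library left out: Kdm3a without any 1 of the 6 (adjusted p = 0.0668 to 0.149), Rpl11 without old replicate 2 (adjusted p = 0.0667), Mt2 without young or old replicate 2 (0.0601 and 0.0608) and Rpa2 without old replicates 1 and 2 (0.0518 and 0.0579). Hes1 did not pass without young replicates 1, 2 and 3 (0.0986, 0.106 and 0.052) or old replicates 1, 2 and 3 (0.0572, 0.111 and 0.0579).

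The largest rises were in Txlnb (at least 107-fold, 24.4 ± 27 CPM; log2 9.74, 8.24 without old replicate 1), Dlc1 (0.0843 to 44 ± 41 CPM), the homeobox gene Meis2 (34.7-fold, 27.1 ± 41.4 CPM) and Nr6a1 (31.5-fold; log2 4.98, 4.37 without old replicate 2). The largest falls were in Gpnmb (at least 304-fold, 58.6 ± 61.9 CPM in young), Mmp12 (at least 228-fold), Fabp4 (27 ± 26.2 to 0.115 CPM), Hsf2bp (30.1-fold; log2 −4.91, −4.24 without young replicate 2) and Ccl2. Meis2 did not pass without young replicates 1, 2 and 3 or old replicate 1 (adjusted p = 0.0836 to 0.156), and its log2 change was 2.05 in place of 5.12 without the last. Gpnmb, Mmp12 and Ccl2, which macrophages make, were highest in 3D young replicate 3 (Gpnmb 18.5, 27.3 and 130 CPM; without it log2 −9.65 for Gpnmb and −9.33 for Mmp12 in place of −10.99 and −10.57), and the adipocyte gene Fabp4 in replicate 2 (9.81, 57.1 and 14 CPM). Ageing genes were not called (7 of 30 higher, 2 lower, 9 and 4 adjusted over the list alone, adjusted p = 0.178). Nor were long-term stem cell genes (1 of 24 and 2, 2 and 6 adjusted over the list alone, 0.15), with Prdm16 4.46-fold lower. Glycolysis (0 of 17, 0.396) and G2/M genes (1 of 24, 0.955) were not called either.

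In edgeR 921 of 12741 genes passed (578 higher, 343 lower), 1489 in DESeq2 and 1877 in edgeR without a filter. The count fell to 556, 403 and 400 without young replicates 1, 2 and 3 and to 522, 329 and 524 without old replicates 1, 2 and 3. None of the 8 called lists holds with an estimated correlation.

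The interaction tests whether the age difference in 3D differs from that in primary cells, gene by gene. Values follow the order primary young, primary old, 3D young, 3D old. Hes1 stood at 73.4, 6.36, 99.2 and 220 CPM (log2 interaction 4.67 ± 0.45 SE, adjusted p = 0.000104) and Cdkn1b, which holds cells out of cycle, at 367, 214, 193 and 345 CPM (1.62 ± 0.28 SE, 0.00291). Vwf went the other way at 11.8, 22.4, 5.79 and 0.464 CPM (−4.50 ± 0.57 SE, adjusted p = 0.000502), as did Ehd3 (4.55, 26.8, 20.5 and 3.6 CPM, −5.05 ± 0.64 SE), Ghr (5.29, 31.3, 7.17 and 6.25 CPM, −2.75 ± 0.53 SE) and Selp (7.35, 37.2, 141 and 140 CPM, −2.33 ± 0.67 SE, adjusted p = 0.0284). Hlf was at 318, 151, 53.4 and 77.6 CPM (1.61 ± 0.33 SE), Prdm16, needed to maintain stem cells, at 116, 79.5, 34.9 and 7.76 CPM (−1.62 ± 0.42 SE), Csf2rb at 95, 14.4, 170 and 243 CPM (3.22 ± 0.42 SE) and the homing receptor Cxcr4 at 47.4, 38.7, 5.13 and 18.1 CPM (2.11 ± 0.36 SE). Without primary young replicate 1, primary old replicate 2, 3D young replicate 2 or 3D old replicate 1 or 3 the adjusted p of Selp was 0.0507 to 0.064, and without primary young replicate 3 its value was −4.02. Ptprc passed (0.72 ± 0.23 SE, adjusted p = 0.048), with 0.0534 to 0.13 without any 1 library other than primary young replicate 1. Kit (0.153), Slamf1 (0.441), Cd48 (0.14), Procr (0.993), Mki67 (0.336, and 0.0237 without primary young replicate 2), Cdkn1c (0.957) and Ly6a (0.813) did not pass.

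Immediate early genes had 7 of 16 members with a negative interaction and 0 positive, 8 adjusted over the list alone (list adjusted p = 0.000155, adjusted p = 0.544 with an estimated correlation). Socs3 stood at 2.94, 17.8, 60 and 63.2 CPM (−2.50 ± 0.45 SE), Junb at 56.6, 134, 267 and 274 CPM (−1.20 ± 0.22 SE) and Fos at 54.4, 173, 59.4 and 53.4 CPM (−1.82 ± 0.35 SE). Ribosomal protein genes had 7 of 22 positive, 9 adjusted over the list alone (0.000197, adjusted p = 0.746 with an estimated correlation), with Rpl11 at 1970, 1681, 1693 and 2307 CPM (0.68 ± 0.13 SE). Among the largest interactions were Tmem65 (72.1, 4.56, 6.2 and 20.4 CPM, 5.71 ± 0.50 SE) and Zfp85 (1.64, 21.1, 11 and 1.76 CPM, −6.30 ± 0.60 SE). Lists not called include ageing (3 of 30 positive, 9 negative, adjusted p = 0.28), interferon (0 of 22 and 6, 0.162), S phase (2 of 24 and 6, 0.0668), G2/M (0 of 24 and 1, 0.0668) and quiescence genes (5 of 15 and 2, 0.585). In edgeR 2450 of 12741 genes passed (1316 positive, 1134 negative).

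Over the 3465 genes that differed with age in primary cells, the age effects in primary and 3D cells had a Pearson correlation of 0.068 across genes, which are not independent replicates (Spearman 0.018), and 49.4% had the same sign. On mean log2 CPM the correlation was 0.027 over these genes (exact permutation of age labels p = 0.6, smallest possible 0.1) and 0.015 over all 12741 (p = 0.48, smallest possible 0.01). Genes called in both were 325, of which 101, such as Plscr2 and Trp53inp1, were higher in both (76.8 if independent), 59 lower in both (47.7) and 165, such as Hes1, opposite (126).

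Stromal ATAC data address whether open regions differ between primary, 2D and 3D cells. Fewer peaks were called in primary cells (37202 ± 8812, n = 3) than in 2D (141245 ± 19324) and 3D (112652 ± 19918), ratios of 3.8 and 3.03 (exact permutation p = 0.1 each, the smallest possible), and 3D had 0.798 times the peaks of 2D (p = 0.2). Per 1e6 filtered tags 3D had 1.92 times the peaks of primary and 0.418 times those of 2D. Filtered tags per library were 31.7 to 44.6 M in primary, 18.1 to 46.9 M in 2D and 54.7 to 64.5 M in 3D. Of primary consensus peaks 84.3% were met by 2D and 88.1% by 3D, of 2D peaks 19.8% by primary and 62.5% by 3D, and of 3D peaks 27.5% by primary and 84.5% by 2D. With the 20000 strongest peaks of each library these were 50.1% and 64%, 47.2% and 67.8%, and 61% and 68.4%. Mean Jaccard overlap was 0.22 between primary and 3D libraries and 0.151 between primary and 2D libraries, and 0.325 and 0.224 with the 20000 strongest peaks, and by both every 3D library lay above every 2D library (exact permutation p = 0.1).

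The mean number of regions with a peak per primary, 2D and 3D library was 11, 40 and 32 of the 62 nearest Cxcl12, 7.67, 29.3 and 24.7 of 51 at Kitl, 5, 6.67 and 6.33 of 15 at Lepr and 1.33, 5 and 6.67 of 8 at Acta2. Near Cxcl12 regions 118776 and 151354 bp from the start site were open in 3 primary, 0 2D and 3 3D libraries. Their fold enrichment was 10.7 and 6.46 in primary and 3.58 and 7.91 in 3D. Open in 3, 3 and 0 were a Cxcl12 region at 155163 bp and the Lepr promoter. A Lepr region at −22658 bp was open in 3, 0 and 0, and a Kitl region at 40447 bp in 3, 0 and 1.

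Regions present in all 3 libraries of a group and absent from all 3 of the other numbered 69460 for 2D without primary and 1307 the other way, 43749 for 3D without primary and 636 the other way, and 4262 for 3D without 2D and 17466 the other way. Leaving out 1 library loosens the rule, so counts can only rise. They rose from 1307 to 3723 and 636 to 2396 (primary replicate 3) and 4262 to 7752 (3D replicate 2). The 17466 became 28842 (2D replicate 1) and 26782 (3D replicate 3). Of the 4262 regions in 3D and not in 2D, 19.5% were open in at least 2 primary libraries, against 1.12% of the 17466 regions in 2D and not in 3D.

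Genes nearest to regions lost in 2D against primary were lower in RNA in 28 of 30 called cases (93.3%), while genes nearest to gained regions were higher in 47.9% (2812 higher, 3056 lower; Fisher exact odds ratio 12.9, p = 2.6e-06). For 3D against primary 25 of 29 genes for 636 lost regions were lower (86.2%, Fisher exact odds ratio 6.35, p = 5.39e-05). For 3D against 2D 64.8% of called genes at gained regions were higher (158 and 86) and 48% at lost regions lower (Fisher exact odds ratio 1.7, p = 0.000339). Among other called genes 46.1%, 48.9% and 55% were higher. Signal per region was not tested, and depth was unequal.

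**Figure D4:**
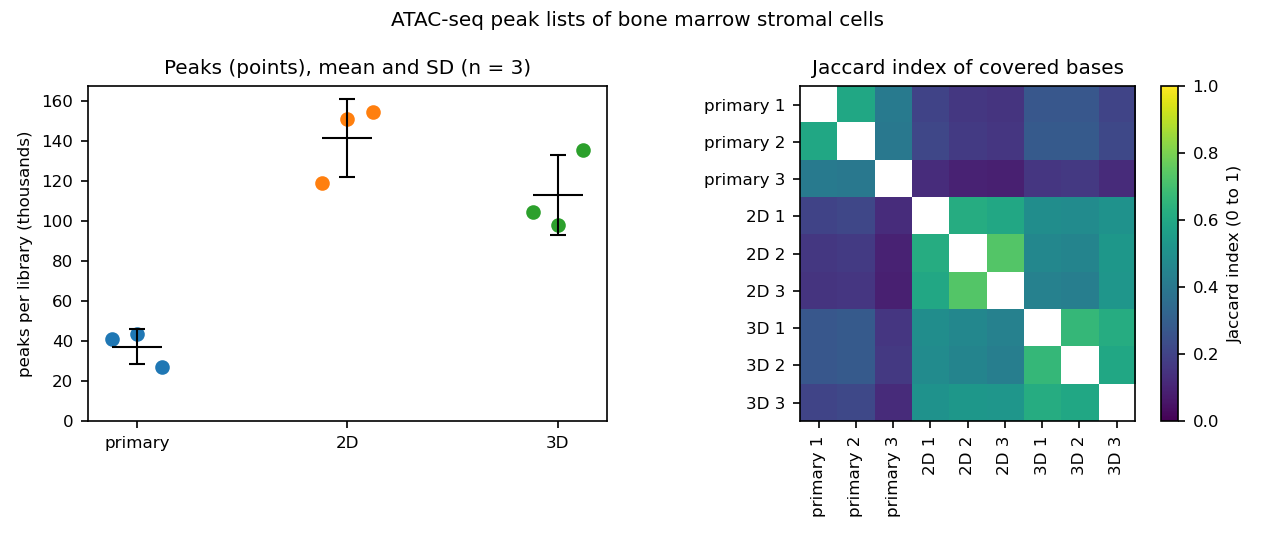
Peaks per ATAC library in units of 1000 for primary, 2D and 3D stromal cells (n = 3 each), and a heatmap of Jaccard overlap between all pairs of libraries. Primary libraries have the fewest peaks and overlap more with 3D than with 2D libraries.

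The single-cell libraries address which cells arise in the gel at each age. After filtering 11117 young and 10747 middle-aged cells were used (median 18384 and 22211 UMIs). Cells resembling stem cells and multipotent progenitors, named by markers such as Hlf and Mecom, made up 21.1% (20.3 to 21.8) of young and 15.2% (14.5 to 15.8) of middle-aged cells. Neutrophil-like cells were 2.26% (1.99 to 2.55) and 6.68% (6.22 to 7.17), and megakaryocyte-like cells 4.34% and 2.79%. Progenitors of granulocytes and monocytes were 21.1% and 22.9%, mast cell and basophil-like cells 4.41% and 3.41%, monocyte and macrophage-like cells 1.15% and 1.13%, and 45.7% and 48% of cells were in clusters left without a name. Intervals are exact binomial 95% intervals and cover counting error only, and with 1 library per age no test of age was made. Over 5 other random seeds the stem cell and progenitor share was 18.7 to 28.2% and 13.1 to 19%, that of neutrophils 1.89 to 2.99% and 6.29 to 7.86% and that of granulocyte-monocyte progenitors 11.4 to 18.8% and 12 to 21.6% (none with seed 2). Leiden resolution 0.5 gave 9.89% and 6.76% for stem cells and progenitors and 19.5% and 15.7% for mast cells and basophils (2.02% and 1.75% with seed 2). Resolution 1.5 gave 4.34% and 4.51% for monocytes and macrophages (0.56% and 0.758% with doublets kept).

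Over all cells 2533 genes had at least 50 CPM in a library, and 9 were at least 2-fold higher in the middle-aged library. They include the neutrophil granule genes Ltf (7.2 to 94.9 CPM), Ngp (170 to 961), Camp (169 to 771), Lcn2 (121 to 535) and S100a9 (5050 to 12200 CPM), and also Tpm3-rs7 (20.5 to 222) and Wdfy1 (10.4 to 55.1). Gm2a was the single lower gene (52.4 to 18.6 CPM). In stem cell and multipotent progenitor-like cells (2341 and 1629 cells) 4 genes were higher, Tpm3-rs7, Wdfy1, S100a9 (92.1 to 263 CPM) and S100a8 (115 to 237), and 0 were lower. Tpm3-rs7 was 9.7-fold to 13.3-fold higher in every named class, so its rise is not particular to these cells. Wdfy1 was 5.58-fold higher here, 5.64-fold in granulocyte-monocyte progenitor-like and 4.73-fold in neutrophil-like cells. S100a9 was at 103 and 270 CPM in mast cell and basophil-like and 152 and 235 in megakaryocyte-like cells. Pf4 was at 444 and 235 CPM in stem cell and progenitor-like, 939 and 526 in mast cell and basophil-like and 7130 and 7420 in megakaryocyte-like cells. RNA carried over from other cells was not removed, so neutrophil and megakaryocyte genes cannot be read as a change in the progenitors.

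Ranking lists within 1 library per age is no test of age. In stem cell and progenitor-like cells the median log2 ratio of middle-aged to young was above the central 95% of 10000 expression-matched random lists for granulocyte-monocyte (0.36, 13 of 17 genes higher, S100a8 and S100a9 among them, and 0.18 in megakaryocyte-like cells), immediate early (0.21, 11 of 15), lymphoid (0.18, 7 of 8), NF-kB (0.16), cholesterol (0.14, 16 of 20), ageing (0.13, 6 of 9), MYC (0.11) and S phase genes (0.08). Below it were megakaryocyte (−0.41, 9 of 10 lower), hypoxia (−0.12), long-term stem cell (−0.10, 13 of 17 lower), homing (−0.09) and ribosomal protein genes (−0.03). In monocyte and macrophage-like cells (128 and 121 cells) 70 genes were at least 2-fold higher and 3 lower, and all 20 interferon genes were higher (median log2 2.45): the ubiquitin-like Isg15 16.9 to 324 CPM, Rsad2 1.99 to 56.8 and the chemokine Cxcl10 9.45 to 107, beside the interleukin Il1b at 67.2 to 1150 CPM.

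**Figure D5:**
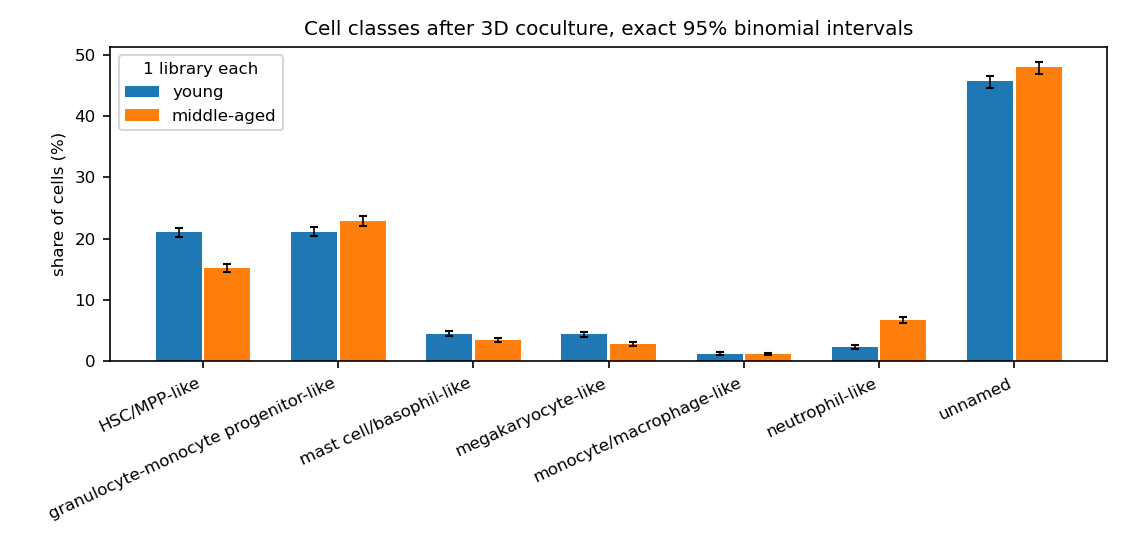
Share of cells in each named class, in percent, in the young and the middle-aged library, with exact 95% binomial intervals that cover counting error only.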

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

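For macrophage genes in 3D stromal cells the tests of contamination and of a rise in every library were chosen after the result was seen, and that of a single library before. Of 14 fixed macrophage markers 5 were called higher in 3D than in 2D cells, most in 3D replicate 3. Hypothesis 1, monocytes or macrophages in that library, cannot be told apart: 12 of 14 markers were at least 2-fold above the other 3D libraries, which restates the pattern. Hypothesis 2, a single library behind the calls, cannot be told apart, since 2 of 5 called genes were still called without it. Hypothesis 3, a rise in the stromal cells of every library, has little support: of 14 markers 8 stood above every 2D library in 3D replicate 2, 2 in replicate 1 and 1 in both. A rise in part of the libraries stays open.

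For blood and vessel genes in primary stromal cells all 3 tests were chosen after the result was seen. Hypothesis 1, platelets or megakaryocytes in the primary sorts, fits: of 12 fixed platelet markers the 7 in the pattern were all lowest in primary replicate 1, close to a single observation since they vary together. Hypothesis 2, a single mixture of blood and vessel cells in varying amounts, has little support, since the ratio of primary replicate 3 to replicate 1 was 4.41 times larger for platelet markers than for hemoglobin. Hypothesis 3, loss of these genes by stromal cells in culture, cannot be told apart: hemoglobin was at least 135-fold higher in every primary than in every cultured library, which a loss of other cells would give too.

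For the age difference, the test of depth was chosen after the result was seen, those of spread and effect size before. More genes changed with age in primary (3465) than in 3D stem cells (921). Hypothesis 1, depth, has little support: with libraries thinned to equal total counts 3106 and 648 passed, a ratio of 4.79. Hypothesis 2, larger spread between 3D libraries, has little support (ratio of coefficients of variation 0.79). Hypothesis 3, a larger age difference in primary cells, cannot be told apart: a net variance 2.4 times that in 3D nearly restates the pattern. A library batch might give it too, and no label names one.

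The age difference differed between primary and 3D stem cells in 2450 genes. In the interaction the immediate early and ribosomal protein lists had adjusted p = 0.000155 and 0.000197, and adjusted p = 0.544 and 0.746 with an estimated correlation.

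Regrouping the libraries was planned before the results were seen. With 3 libraries against 3 there are 10 splits, too few to give a p-value under 0.1. For genes, 1 of 10 splits was as large as the real one in each comparison, and the highest other count was 0. For lists the real count, the highest other and the number of splits as large were 15, 16 and 2 (2D against primary), 15, 16 and 3 (3D against primary), 11, 20 and 4 (3D against 2D), 2, 2 and 4 (old against young primary), 14, 10 and 1 (3D against primary young), 12, 11 and 1 (3D against primary old) and 8, 4 and 1 (old against young 3D). For the interaction, 1 of 40 regroupings was as large for genes (2450, highest other 649) and 26 of 40 for lists (2, highest other 7).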

How the results depend on the processing

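Of the other settings, 299 of the results of the comparisons stayed the same and 92 moved. No comparison and no bulk list was reversed. The whole-series count matrix was not run, as its counts were identical. Lists were not retested with libraries left out.

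A test against a 2-fold change left 5139 genes in 3D against primary stromal cells, 796 in 3D against 2D, 861 in old against young primary stem cells, 2081 and 1510 in 3D against primary young and old cells, 84 in old against young 3D cells and 608 in the interaction. For old against young 3D cells DESeq2 called 1489 genes and edgeR without a filter 1877.

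Leaving out 1 library gave 9218 to 9872 genes in 2D against primary, 8555 to 9043 in 3D against primary and 2168 to 3712 in 3D against 2D. In stem cells it gave 2731 to 3297 for age in primary, 5400 to 5863 for 3D against primary young, 4311 to 4542 for 3D against primary old, 329 to 556 for age in 3D and 1802 to 2468 for the interaction. The position of 3D ranged from 0.75 to 0.782 and the correlation of age effects from 0.033 to 0.075. Counts with only replicates 2 and 3 were 8850, 7719 and 2713 in the 3 stromal comparisons.

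With an estimated inter-gene correlation 9 stromal lists stayed called (4, 4 and 1, comparisons in the order above). So did 8 stem cell lists (0, 5, 3, 0 and 0). With the replicate block as well 2 stromal lists stayed (1, 0 and 1) and 7 stem cell lists (0, 3, 4, 0 and 0). The fry test called 23 lists in 2D against primary, and in stem cells 58 in all, 4 for age in primary and 23 for 3D against primary young. Besides lists named in the report, the block alone called senescence genes in 3D against primary old and mast cell genes for age in 3D, and 13 lists in 3D against 2D in place of 11.

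Peaks above the median −log10 q gave ratios of 5.47 (2D to primary) and 4.54 (3D to primary). Peaks per 1e6 filtered tags gave 1.92 (3D to primary) and 0.418 (3D to 2D). Without 1 library the ratios ranged over 3.34 to 4.13 (2D to primary), 2.67 to 3.3 (3D to primary) and 0.717 to 0.849 (3D to 2D). With the 20000 strongest peaks the overlaps were, in the order of the report, 50.1, 64, 47.2, 67.8, 61 and 68.4%. With peaks in all 3 samples 88% and 92.4% of primary peaks were met by 2D and 3D. Without 1 library these overlaps ranged over 79.7 to 90.6%, 84.3 to 94.2%, 13.3 to 24%, 52.6 to 70.1%, 18.4 to 33.2% and 73.6 to 89.6%. Regions in 2 or 3 libraries of a group and 0 of the other numbered 4143 (primary, not 2D), 2745 (primary, not 3D), 10042 (3D, not 2D) and 32630 (2D, not 3D). Leaving out 1 library loosens the 3 against 0 rule, so its counts can only rise. In report order they were 69922 to 94392, 1344 to 3723, 44172 to 54924, 661 to 2396, 4418 to 7752 and 18099 to 28842.

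In single cells the ratio of middle-aged to young shares of stem cells and progenitors was 0.664 at Leiden resolution 1.5 and 0.673 with seed 3. For granulocyte-monocyte progenitors it was 1.24 with doublets kept and 1.02 with seeds 3 and 5, for mast cells and basophils 0.945 with seed 1, and for monocytes and macrophages 1.35 with doublets kept. Of other results here 104 stayed and 73 moved. With UMIs thinned to 5000 per cell the lymphoid list over all cells was reversed (median log2 0.01). Seeds were added after clusters moved with rounding error. P-values with an estimated correlation moved with the linear algebra kernel, now fixed, and no call changed.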

Other observations

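Replicate 1 of every stromal RNA group carried more Xist and less of the Y-linked Ddx3y than the other 2 libraries: Xist was 146, 13.3 and 14.5 CPM in primary, 7.91, 0.393 and 0.394 in 2D and 23.7, 1.97 and 0.142 in 3D, and Ddx3y 12.6, 46.8 and 47.4, then 1.77, 33.4 and 38.6, then 1.09, 84.9 and 47.1 CPM. All stem cell libraries had Xist at 0 to 1.26 CPM and Ddx3y at 31.5 to 107 CPM.

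The beta hemoglobin Hbb-bt stood at 1470 to 2210 CPM in 3D stem cell libraries and at 39.7 to 99.4 CPM in primary ones, while Hbb-bs was at 0.758 to 7.42 CPM and Hba-a1 at 0 to 3.45 CPM in 3D.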
